A study of Mus musculus with 9 samples.

How the data were processed

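The series holds 9 samples of total RNA from bone marrow dendritic cells of female C57BL/6 mice, 3 untreated, 3 treated with E. cuniculi and 3 treated with C. parvum strain Iowa. Per the labels, the RNA was column-purified and turned into biotin-labelled cRNA by in vitro transcription with a GeneChip kit. The submitters' processing notes name RMA and MAS5, with no role or version. The array platform, the scanner settings and the probe annotation are not given in the sources used here.

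The deposited values are intensity values on a linear scale, 1 per probe set and array, for 45101 probe sets. Their mean without the lowest and highest 2% of probe sets is 100 on every array and their distributions differ between arrays. MAS5 global scaling gives values of this kind and RMA, which gives quantile-normalized log2 values, does not, so the values were read as MAS5-type signals. No detection calls were used here, so a low signal cannot be told from background. Global scaling sets this trimmed mean equal between arrays, and the quantile normalization described below sets the whole distributions equal. A change of most transcripts in 1 direction is therefore hidden in the normalized values, and can be hidden in the deposited ones. Signals printed with ± are means and SDs of the deposited values, and log2 fold changes come from the normalized values, on the log2(value + 16) scale. This scale understates the changes of dim probe sets.

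A probe set is a group of short probes read together. Suffixes A_AT, S_AT and X_AT in an ID mark probe sets that can match more than 1 transcript. The 64 control probe sets were set aside: 18 hybridization spikes, 24 poly-A spikes, 19 mouse control genes and repeats and 3 TrpnX negative controls. The other 45037 were tested. To each signal 16 was added, the log2 was taken, and arrays were quantile-normalized to each other. One limma model (version 3.58.1, R 4.3.3) with the group as its term was fitted to all 9 arrays with lmFit and eBayes. The comparisons were C. parvum against untreated, E. cuniculi against untreated and C. parvum against E. cuniculi. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 45037. All adjusted p-values in the text are from limma. Figures were drawn with matplotlib 3.10.9.

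The tests, the alternatives planned for them, 26 gene lists and 17 key genes were fixed before the data were examined. The plan foresaw 1 probe set per gene and a test of each list. The files do not pair probe sets with genes, and 0 of the probe set IDs were found in the reference table of gene symbols used here. The fallback of the plan was therefore used, which tests all probe sets by ID. The gene lists and key genes were not tested. The rule for probe sets to be named took, per comparison and direction, the 8 with the largest fold change among those that passed the threshold, whose 3 arrays of one group all lay above the 3 of the other and whose brighter group mean was at or above the median. Of these 8, the first 2 per direction are printed. The other parts of the rule named genes by list or symbol and could not be applied.

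Overlaps between the comparisons that share the untreated arrays were set beside 100 simulations of unchanged groups and beside the overlap of independent lists. In each simulation all 9 arrays were drawn with normal noise around the untreated means, independent between arrays and between probe sets. RNA integrity was measured as the difference between the 3′ and 5′ control probe sets of Gapdh and beta-actin, as deposited and after quantile normalization, with two-sided exact permutation tests. Mean spike signals of the groups were compared in a linear model with replicate 1 against the others as a term. The model was tested on simulated arrays built like the C. parvum and untreated arrays, with 200 of 45037 probe sets changed and 5 runs. It recovered 17.6% of 1.5-fold, 77.6% of 2-fold and 98.5% of 4-fold changes, with a mean of 8.6 false calls per run and 0 calls of the wrong sign. In this setting, with few probe sets changed, a 1.5-fold change was thus mostly missed. The adjusted threshold is easier to pass where more probe sets change, so these shares do not carry over to the comparisons with E. cuniculi.

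Alternatives tried were median scaling without quantile normalization, pseudocounts of 1 and 64, leaving out the dimmest 40% of probe sets, a replicate block, a trended robust prior, array weights, a fit of only the groups compared, a 2-fold threshold, an adjusted p under 0.01, and leaving out each array. Added after seeing the data were the deposited scaling with no normalization, scaling to the hybridization spikes, scaling to the poly-A spikes with the replicate block, a covariate for replicate 1, and replicates 2 and 3 only.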

Results

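Messenger RNA of mouse dendritic cells was measured on 9 one-colour arrays. Dendritic cells are the immune cells that take up microbes and present their antigens to T cells. They came from bone marrow of female C57BL/6 mice. The cells were left untreated, or were treated with C. parvum strain Iowa (Cryptosporidium parvum, an apicomplexan parasite of the intestine) or with E. cuniculi (Encephalitozoon cuniculi, a spore-forming intracellular parasite of the microsporidia). Each of these 3 groups had 3 arrays. The labels give 24 h for the C. parvum treatment, whereas a time for the other groups and the doses are not given in the sources used here. The question named by the design was how the cells responded to C. parvum, with untreated cells and E. cuniculi as control groups. Signals were linear intensities of 45101 probe sets with a trimmed mean of 100 on every array, and the median signal per array lay between 10.9 and 16.1. The files do not pair probe sets with genes, so probe sets are given by ID, at most 2 higher and 2 lower per comparison, and the gene lists fixed for these cells were not tested. Those with the suffix A_AT, S_AT or X_AT can match more than 1 transcript. Nothing says that the 3 arrays of a group came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision.

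Replicate arrays of a group had Spearman correlations across probe sets between 0.890 and 0.918, and at most 1.67% of their values were identical. The first principal component held 54.5% of the variance. Untreated arrays lay at -54.2 to -44.0 on it, C. parvum arrays at -19.3 to -11.0 and E. cuniculi arrays at 54.2 to 77.2. The second component, with 11.7%, set the C. parvum arrays (-45.2 to -18.4) apart from the untreated (16.7 to 23.2) and E. cuniculi arrays (4.0 to 18.4).

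**Figure D1:**
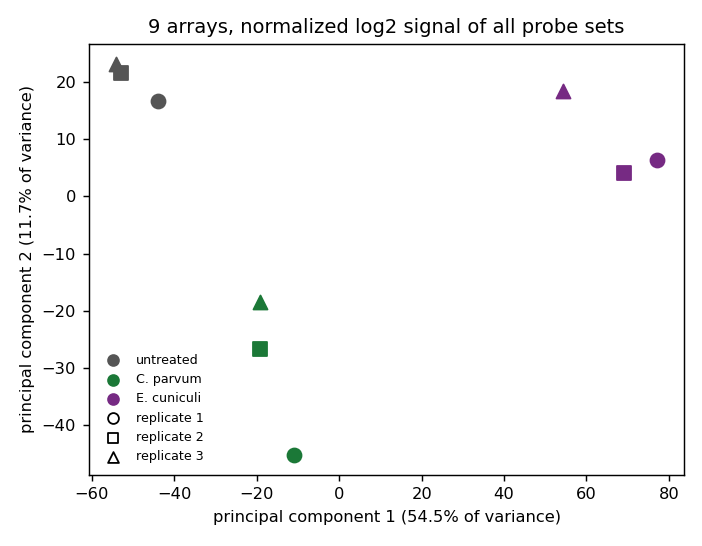
First 2 principal components of the normalized log2 signals of 45037 probe sets, with 1 point per array, colour for the group and shape for the replicate number. The 3 groups occupy separate places, with the E. cuniculi arrays at 54.2 or above on the first component and every other array at -11.0 or below.

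C. parvum raised 479 probe sets and lowered 194 against untreated cells, together 1.49% of the 45037 tested, at an adjusted p under 0.05 in limma. The increases were the larger changes. Of the probe sets that rose, 278 did so by 2-fold or more and 95 by 4-fold or more, whereas 26 fell by 2-fold or more and 0 by 4-fold or more. The median log2 fold change was 1.11 among the higher and -0.67 among the lower. There were 9 probe sets that went from a mean signal under 20 to one of 200 or more, and 0 that went the other way. Probe sets were ranked by the fitted change on the log2(value + 16) scale. Probe set 1436058_AT, first among the increases, rose from 60.1 ± 9.6 to 4621.5 ± 484.9 (SD, n = 3 arrays per group), a log2 fold change of 6.00 with a standard error of 0.14 (adjusted p = 3.58e-07). Probe set 1418293_AT rose from 16.8 ± 14.1 to 1854.2 ± 387.3, with a log2 fold change of 5.91 and a standard error of 0.33 (adjusted p = 2.73e-05). The untreated signals of 1418293_AT (1.7, 19.3 and 29.5) lay near background, so the size of its change depended on the pseudocount (4.57 with 64 and 7.26 with 1) and the order of these increases carries no information. The largest decreases were smaller. Probe set 1426065_A_AT fell from 509.5 ± 119.1 to 157.8 ± 40.1 (log2 fold change -1.59, standard error 0.20, adjusted p = 0.0052). Probe set 1426657_S_AT fell from 272.7 ± 100.1 to 77.4 ± 18.7 (log2 fold change -1.58, standard error 0.26, adjusted p = 0.0207). On all 3 treated arrays each of these 4 probe sets lay beyond all 3 untreated arrays, which the rule for naming them required. Of all probe sets 19.0% did so, where chance gives 10%. Without the probe sets' names, no theme could be given to these changes.

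The count for C. parvum fell whichever array of the groups compared was left out. It was 414, 306 and 377 without untreated replicate 1, 2 and 3, and 420, 320 and 469 without C. parvum replicate 1, 2 and 3. Leaving out an array leaves 2 in its group, so the effect of fewer arrays cannot be told from that of a single array. The decrease of 1426657_S_AT no longer passed without untreated replicate 2 (log2 fold change -1.54, adjusted p = 0.103), untreated replicate 3 (-1.33, 0.0593), C. parvum replicate 1 (-1.39, 0.0732) or C. parvum replicate 2 (-1.65, 0.0716). Its fold change stayed near the -1.58 of all arrays, and the adjusted p ranged from 0.00242 to 0.198 in 24 alternatives. Replicate 1 differed in its spiked-in transcripts, described below, and may be a preparation of its own. In replicates 2 and 3 only, 202 probe sets were higher and 14 lower. There 1426065_A_AT missed the threshold (log2 fold change -1.64, adjusted p = 0.0579, range over alternatives 0.000234 to 0.0579). With replicate 1 against the others as a covariate, 549 were higher and 273 lower. The balance of directions depended on the scaling: with arrays scaled to their hybridization spikes, 212 were higher and 375 lower.

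E. cuniculi changed 8545 probe sets against untreated cells, 19.0% of those tested, with 3691 higher and 4854 lower. Changes of 2-fold or more were about as common upward (1296) as downward (1353), while 4-fold changes were more often increases (394) than decreases (128). There were 52 probe sets that went from a mean signal under 20 to 200 or more, and 10 that went the other way. First by the same ranking, probe set 1460667_AT rose from 12.4 ± 12.0 to 8379.7 ± 532.6 (log2 fold change 8.10, standard error 0.31, adjusted p = 1.13e-06). On the C. parvum arrays its signal was 18.3 ± 7.9, which did not pass against untreated cells (log2 fold change 0.28, adjusted p = 0.81). Probe set 1435529_AT rose from 5.5 ± 3.9 to 4243.8 ± 896.7 (log2 fold change 7.44, standard error 0.48, adjusted p = 1.24e-05), and was higher with C. parvum too, at 236.1 ± 162.8 (log2 fold change 3.25, adjusted p = 0.0108). Untreated signals of both lay near background, so the sizes depended on the pseudocount (6.62 with 64 and 9.68 with 1 for 1460667_AT, 5.78 and 9.29 for 1435529_AT) and their order carries no information. Probe set 1421186_AT fell from 1001.8 ± 421.2 to 41.5 ± 8.2 (log2 fold change -4.03, standard error 0.39, adjusted p = 0.000124). Probe set 1426657_S_AT, also lower with C. parvum, fell to 2.7 ± 2.2 with E. cuniculi (log2 fold change -3.87, standard error 0.26, adjusted p = 1.72e-05). That level lay within the range of the array's TrpnX negative controls (up to 8.2), so the size of the decrease depended on the pseudocount (-2.26 with 64 and -6.35 with 1). The 3 arrays of each group did not overlap for 32.6% of all probe sets, against 10% by chance.

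Leaving out 1 array at a time gave 6417 to 8810 changed probe sets for E. cuniculi. Replicates 2 and 3 only gave 2655 higher and 3401 lower, and replicate 1 as a covariate 4118 higher and 5407 lower. The balance of directions moved with the scaling. Scaling to the hybridization spikes gave 1385 higher and 9335 lower, with the median of all probe sets at -0.11 on the log2 scale instead of 0.00, and scaling to the median gave 2242 higher and 5559 lower.

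**Figure D2:**
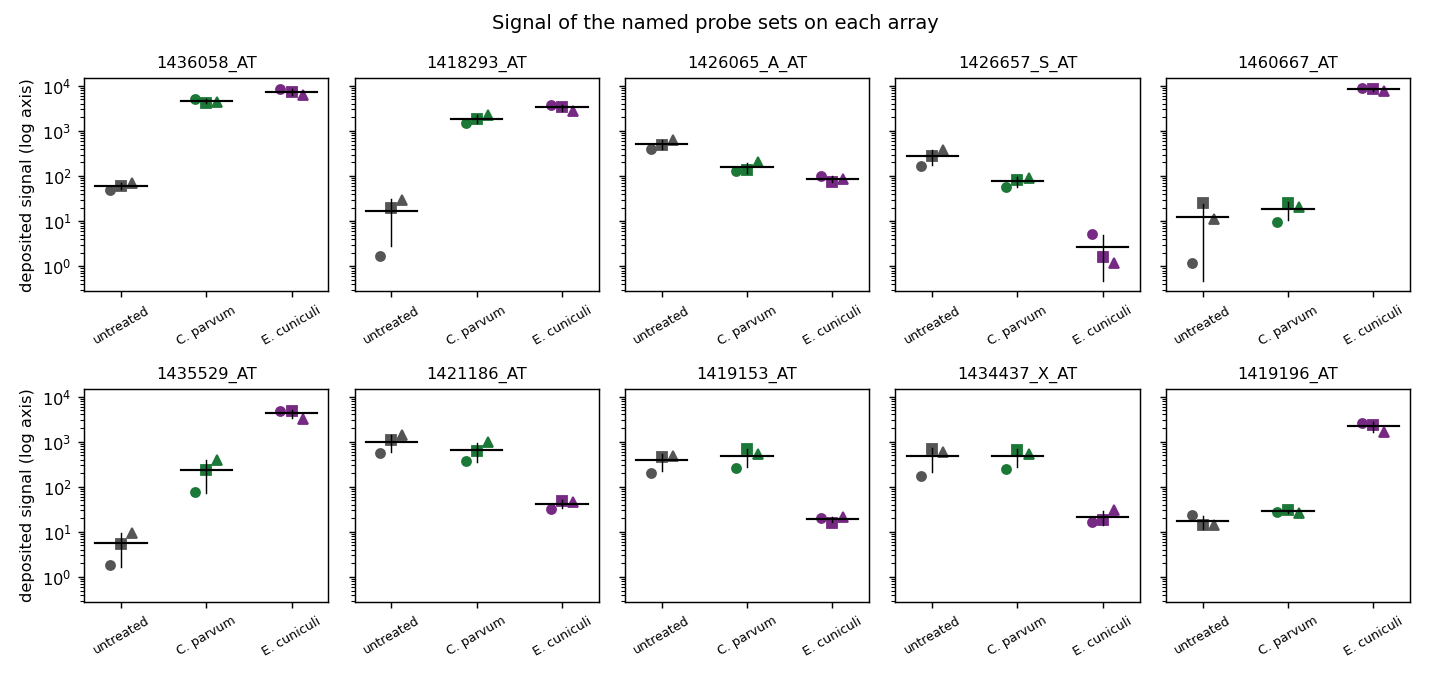
Deposited signal (log axis) of the 10 probe sets given by ID, with 1 panel per probe set and 1 point per array. Shapes are replicate numbers (circle 1, square 2, triangle 3), horizontal lines are means of 3 arrays and vertical bars are 1 SD on each side. Probe set 1460667_AT stood at 8379.7 with E. cuniculi and at 18.3 with C. parvum, while 1436058_AT was high with both organisms.

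The direct comparison of the organisms found 3144 probe sets higher and 2685 lower with C. parvum than with E. cuniculi, 12.9% of those tested. Of these, 779 were higher and 827 lower by 2-fold or more, and 76 were higher and 164 lower by 4-fold or more. Probe set 1419153_AT stood at 488.5 ± 214.9 with C. parvum and 19.0 ± 2.7 with E. cuniculi (log2 fold change 3.74, standard error 0.39, adjusted p = 0.000436), beside 383.7 ± 159.0 in untreated cells. Probe set 1434437_X_AT stood at 485.7 ± 214.0 and 21.5 ± 7.3 (log2 fold change 3.64, standard error 0.51, adjusted p = 0.00197), beside 474.7 ± 267.3 in untreated cells. In both of them E. cuniculi lowered the signal, and the C. parvum value did not pass against untreated cells (adjusted p = 0.799 and 0.961). In the other direction, 1460667_AT was lower with C. parvum by a log2 fold change of -7.82 (standard error 0.31, adjusted p = 9.96e-06). Probe set 1419196_AT stood at 28.3 ± 2.3 with C. parvum and 2185.6 ± 520.2 with E. cuniculi (log2 fold change -5.56, standard error 0.19, adjusted p = 7.94e-06), beside 17.2 ± 5.5 in untreated cells. The dimmer group of these probe sets lay near the array medians, so the sizes depended on the pseudocount (2.64 with 64 and 4.50 with 1 for 1419153_AT, -4.50 and -6.17 for 1419196_AT). The arrays of these groups did not overlap for 27.3% of all probe sets, against 10% by chance.

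Leaving out 1 array at a time gave 3705 to 5554 probe sets that differed between the organisms, and only leaving out C. parvum replicate 2 (3705) moved the count by over 1.5 times. Replicates 2 and 3 only gave 1713 higher and 1407 lower with C. parvum, and replicate 1 as a covariate 3725 higher and 3127 lower. With arrays scaled to their hybridization spikes, 4364 were higher and 1013 lower.

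The response to C. parvum overlapped largely with that to E. cuniculi. Of the 479 probe sets that C. parvum raised, 413 (86.2%) were also raised by E. cuniculi, and of the 194 it lowered, 168 (86.6%) were also lowered. These 581 stood against 60.2 for independent lists of the same sizes. In 100 simulations of unchanged groups, all 9 arrays were drawn with independent noise around the untreated means. Both simulated comparisons shared the simulated untreated arrays. The overlap was 0 on average, but the simulations gave a mean of only 0.04 calls per comparison. That 0 therefore says nothing about the overlap of longer lists. All 95 probe sets that rose by 4-fold or more with C. parvum also rose with E. cuniculi, with median log2 fold changes of 2.83 and 4.04, and all 26 that fell by 2-fold or more also fell. In the direct test, 201 of the 413 shared increases were lower with C. parvum than with E. cuniculi, and 211 were not called. Of the 168 shared decreases, 83 were lowered less by C. parvum and 84 were not called. Across probe sets, which are not independent replicates, the log2 fold changes of the organisms correlated at 0.627, beside 0.501 in the simulations. Their covariance was 0.104, beside 0.0146 in the simulations. Of the 3691 probe sets higher with E. cuniculi, 80.1% had the same sign with C. parvum, beside 83.9% in the simulations. Of the 4854 lower ones 85.4% did, beside 82.3%. Their median log2 fold changes with C. parvum were 0.21 and -0.226, beside 0.144 and -0.133. The simulated lists held as many probe sets, taken from unchanged ones by their largest t-values. Noise of the shared untreated arrays sets the signs in them, whereas the real lists were chosen for changes with E. cuniculi. The simulated shares and medians are therefore not a like reference and cannot decide whether directions were shared. The simulated covariance includes what shared untreated arrays add when noise is independent between arrays and probe sets, which may not hold for the real arrays. The count for independent lists does not, so part of the excess of shared calls over it may come from these arrays, which are too few to split. That count also spreads the calls over all probe sets. Only 17 of the 673 and 324 of the 8545 calls were among the dimmest 40%, so it is too low for this reason as well. The shared count was 386, 289 and 346 without untreated replicate 1, 2 and 3, and 382 and 296 without C. parvum replicate 1 and 2. It was 209 in replicates 2 and 3 only and 705 with replicate 1 as a covariate. With arrays scaled to their hybridization spikes, 186 shared calls were higher and 359 lower.

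**Figure D3:**
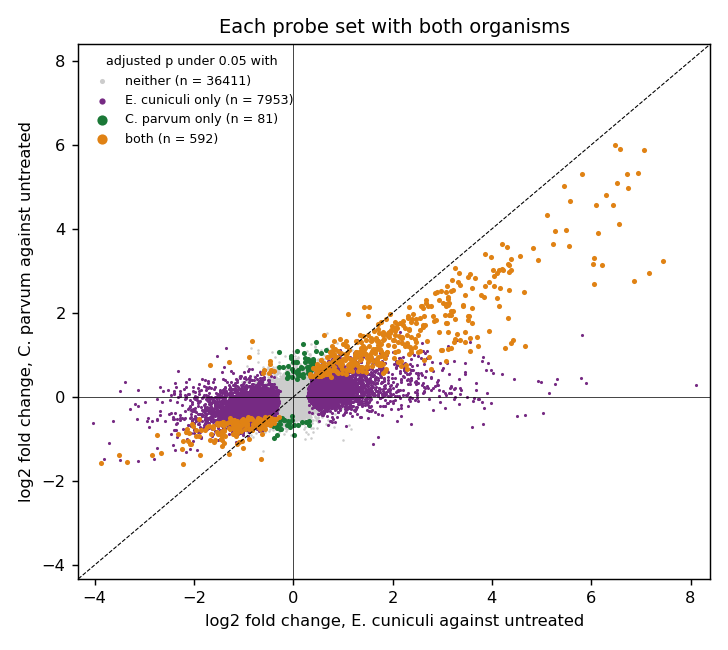
Log2 fold change against untreated cells of each of 45037 probe sets, E. cuniculi on the x axis and C. parvum on the y axis, coloured by the comparison in which the adjusted p was under 0.05. The dashed line marks equal changes. The strongest increases with C. parvum were also increases with E. cuniculi, and many changes with E. cuniculi lay near 0 with C. parvum.

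Much of the E. cuniculi response had no called counterpart with C. parvum. Of the 394 probe sets that E. cuniculi raised by 4-fold or more, 190 (48.2%) were called higher with C. parvum, 136 changed by under 1.5-fold with it, and 344 (87.3%) differed between the organisms in the direct test. Of the 128 that it lowered by 4-fold or more, 18 (14.1%) were called lower with C. parvum and 115 (89.8%) differed directly. These probe sets were chosen for their change with E. cuniculi, which by itself favours a smaller value in the other group. Higher with E. cuniculi than in both other groups were 2153 probe sets, 731 of them by 2-fold or more in both comparisons, and 2694 were lower than in both, 628 by 2-fold or more, beside 220 and 339 for independent lists. Higher with C. parvum than in both other groups were 46 probe sets, 4 of them by 2-fold or more in both comparisons, and 19 were lower than in both, 0 by 2-fold or more, beside 33.4 and 11.6 for independent lists. Each pair of these comparisons shares the 3 arrays of the organism, which favours joint calls, so the values for independent lists are not what unchanged groups would give. Those values also spread the calls over all probe sets, although few dim ones were called, which lowers them. There were 11 probe sets called in opposite directions, all 11 higher with C. parvum and lower with E. cuniculi, beside 67.5 for independent lists, which leave out that the shared untreated arrays make opposite calls rarer. Their median log2 fold changes were 0.77 and -0.58. This count fell whichever array was left out, which also leaves fewer arrays, and it moved with the settings. It was 4, 2 and 4 without untreated replicate 1, 2 and 3, and 4, 4 and 8 without E. cuniculi replicate 1, 2 and 3. Without C. parvum replicate 1, 2 and 3 it was 5, 4 and 9. It was 3 with median scaling, 1 with pseudocount 1, 5 with only the 2 groups compared, 2 at an adjusted p under 0.01, 0 at 2-fold or more, 1 with scaling to the hybridization spikes, 1 with poly-A spike scaling together with the replicate block and 1 in replicates 2 and 3 only. It was higher with the replicate block (18), a trended and robust prior (19), array weights (23) and pseudocount 64 (23).

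Spiked-in transcripts separated replicate 1 from the other replicates in every group. Bacterial poly-A spikes, which are added to RNA before labelling when used as intended, had a mean log2 signal of 6.19 on untreated replicate 1, 6.12 on E. cuniculi replicate 1 and 6.38 on C. parvum replicate 1. On replicates 2 and 3 they were higher by 2.01, 2.10 and 1.86 on the log2 scale in untreated, E. cuniculi and C. parvum arrays, and each of the 24 spike probe sets was lower on replicate 1 in each group. In alternatives added afterwards and in the linear model of the spikes, replicate 1 was therefore treated as if it were a preparation of its own. The main model behind the counts above held no term for it. Replicate 1 held 1 array of each group, so that no test was possible within it. With the groups as a term, 3 probe sets were lower and 0 higher on replicate 1 than on the other arrays, and 5983 had an unadjusted p under 0.05 in limma. The difference between the 3′ and 5′ log2 signals, a measure of RNA integrity, was -0.34 ± 0.06 for Gapdh in untreated cells, -0.37 ± 0.04 with E. cuniculi and -0.37 ± 0.06 with C. parvum (SD, n = 3). For beta-actin it was 0.20 ± 0.03, 0.21 ± 0.01 and 0.22 ± 0.04. Two-sided exact permutation tests against untreated cells gave p = 0.6 and 0.7 for Gapdh and 0.6 and 0.5 for beta-actin, with 0.1 the smallest that 3 against 3 arrays allow. After quantile normalization the Gapdh difference lay above that of untreated cells by 0.08 with E. cuniculi (exact permutation p = 0.1) and 0.126 with C. parvum (0.1). That of beta-actin changed by -0.059 (exact permutation p = 0.1) and -0.029 (0.4).

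**Figure D4:**
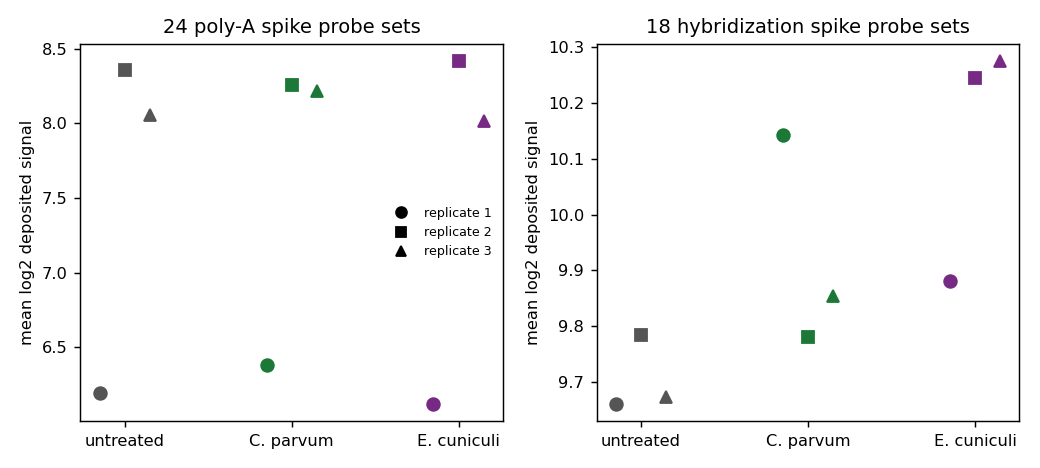
Mean log2 deposited signal of the spiked-in transcripts on each array, poly-A spikes on the left and hybridization spikes on the right, with 1 point per array, colour for the group and shape for the replicate number. The axes do not start at 0. Poly-A spikes on replicate 1 lay between 6.12 and 6.38, below the 8.02 or more of every other array.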

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

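The tests in this part were chosen after the results were seen. The 11 probe sets called in opposite directions with the organisms all differed in the direct test of C. parvum against E. cuniculi (11 of 11), which follows from opposite calls in the same model and adds no evidence. Some control probe sets outside the comparisons lay wholly above or below the untreated arrays on treated arrays. Among 19 mouse control probe sets, 8 had deposited signals above every untreated array on all E. cuniculi arrays and 4 lay below, while on all C. parvum arrays 3 lay above and 0 below. Of the 8, 6 were of actin or Gapdh, whose fitted log2 fold changes after quantile normalization were -0.08 to 0.05. The others were of the murine B2 repeat. After quantile normalization, 1 of these passed (log2 fold change 0.74, limma adjusted p = 0.0274), though not in 7 of 17 alternatives. Its companion did not pass (0.18, 0.229). The 4 below, named after their values were seen, were the 3′ and 5′ ones of transferrin receptor, the middle one of 18S ribosomal RNA and the murine B1 repeat. The 3 above with C. parvum, likewise named, were 2 of Gapdh and 1 of the murine B2 repeat. Among 18 hybridization spike probe sets, 15 were above on all E. cuniculi arrays and 7 on all C. parvum arrays. Chance puts about 1 in 20 probe sets above all untreated arrays, and as many below. Several of these control probe sets read the same spike or gene, so they are not independent draws to set against that share. Among the tested probe sets, after quantile normalization, the arrays did not overlap in either direction for 32.6% with E. cuniculi and 19.0% with C. parvum.

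The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For C. parvum against untreated cells the real split gave 673 changed probe sets and the highest of the others 0. For E. cuniculi against untreated cells these were 8545 and 0, and for C. parvum against E. cuniculi 5829 and 0. In each comparison 1 split, the real one, gave as many.

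E. cuniculi changed 12.7 times as many probe sets as C. parvum at an adjusted p under 0.05. This ratio depended on the threshold. At an unadjusted limma p under 0.05 the counts were closer, 13255 with E. cuniculi and 5884 with C. parvum. At 2-fold or more they were 2649 and 304. The ratio of adjusted calls was 12.7 or more in all 5 scalings tried (that to the poly-A spikes together with the replicate block). With 1 array left out it was 11.3 or more, whichever the array (8.32 with array weights). These values argue against the scaling and a single array as its source. In replicates 2 and 3 only the ratio was 28.0. Replicate 1 held 1 array of each group and so entered both comparisons. Leaving it out also left fewer arrays, so the 28.0 cannot decide whether a separate preparation of replicate 1 was a source. The 3′ to 5′ difference of Gapdh and beta-actin moved by at most 0.033 (log2) between E. cuniculi and untreated arrays as deposited, and after quantile normalization by 0.08 for Gapdh and -0.059 for beta-actin (0.126 and -0.029 with C. parvum). Both sizes are small and their directions opposite, which argues against RNA quality as these probe sets, among the brightest on the arrays, measure it. The 5′ control probe set of 18S ribosomal RNA, described below, passed as lower with E. cuniculi in some alternatives. RNA quality in a wider sense therefore stays open. As a hypothesis, the organisms themselves may account for the ratio, but their doses and the time of E. cuniculi treatment were not given in the sources used here, so a difference in dose or time stays open and untested.

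Poly-A spikes were about 4-fold lower on replicate 1 of every group. Over the groups the smallest difference to replicates 2 and 3 was 1.86 on the log2 scale, while the hybridization spikes, which enter after labelling, moved by at most 0.378, and not in 1 direction. Array brightness or scaling, which would move both kinds of spike alike, is argued against by that value. A separate preparation of replicate 1, with less poly-A spike or more RNA, stays open: among all tested probe sets, replicates 2 and 3 were the most highly correlated pair in 2 of the 3 groups, which does not settle it. No biological explanation was tested, since the difference crosses the groups.

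Hybridization spikes were brighter on E. cuniculi than on untreated arrays by 0.427 on the log2 scale. The standard error was 0.153 in a linear model with replicate 1 against the others as a term (exact permutation p = 0.1 without it, the smallest possible). Less mouse mRNA per total RNA would raise the poly-A spikes as much, and these differed by -0.017 (standard error 0.139). More signal in the brightest probe sets, which the trimmed scaling ignores, would raise the mean signal as much, and it rose by 0.125, less than the spikes by 0.302 (standard error 0.138). That gap was 0.135 on replicate 1 and 0.386 on replicates 2 and 3. With so few arrays and this standard error, it does not settle whether the brightest probe sets contributed. The amounts of labelled RNA and of spike put on the arrays are not given in the sources used here, so a difference in them stays open and untested. The pattern was not unique to E. cuniculi, since their mean log2 signal was higher on C. parvum replicate 1 (10.1) than on E. cuniculi replicate 1 (9.88), and a biological source of it was not tested otherwise.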

How the results depend on the processing

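In none of the 24 alternatives was a changed probe set called in the opposite direction (0 in each comparison), although the balance of higher and lower calls moved with the scaling. Alternatives using the poly-A or hybridization spikes, the deposited scaling, the covariate, or replicates 2 and 3 only were chosen after seeing the data. For C. parvum against untreated cells (673), the count was 323 with median scaling, 277 with pseudocount 1, 1015 with pseudocount 64, 1103 with array weights, 304 at 2-fold or more, 285 at an adjusted p under 0.01, 265 with poly-A spike scaling and the replicate block and 216 in replicates 2 and 3 only. With pseudocount 1, 36.3% of the 673 were kept and 90.6% of the calls were higher, against 55.6% with pseudocount 64. For E. cuniculi against untreated cells (8545), it was 2649 at 2-fold or more and 4995 at an adjusted p under 0.01. For C. parvum against E. cuniculi (5829), it was 3735 with median scaling, 2972 with pseudocount 1, 1606 at 2-fold or more, 2745 at an adjusted p under 0.01, 3855 with poly-A spike scaling and the replicate block and 3120 in replicates 2 and 3 only. For the shared response (581), it was 295 with median scaling, 249 with pseudocount 1, 895 with array weights, 282 at 2-fold or more, 270 at an adjusted p under 0.01, 256 with poly-A spike scaling and the replicate block and 209 in replicates 2 and 3 only. The stricter thresholds lower counts by construction, and for the others the cause was not tested. Leaving out 1 array at a time gave 306 to 696, 6417 to 8810 and 3705 to 5554 changed probe sets in the 3 comparisons and 289 to 610 shared ones. The correlation between the organisms ranged from 0.530 to 0.680.

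Same-numbered arrays deviated from their group means with correlations of 0.007 to 0.346. Those between untreated and E. cuniculi arrays (0.11 to 0.196) all lay above 0.1, but not all of the others did, so the numbers were not taken to pair the arrays. As hints from the data, 9 of 9 arrays correlated best with their own number, and the third principal component (9.95% of the variance) put replicate 1 highest and replicate 3 lowest in every group. With the replicate block, 810, 9681 and 6897 probe sets changed in the 3 comparisons and 707 were shared, each within 1.5 times the count without it.

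For probe sets chosen by the naming rule, the call held in 1115 combinations of probe set and alternative and was lost in 37, all of them decreases with C. parvum. Values of control probe sets stayed on their side of the threshold or within their spread in 355 combinations, moved in 22, lost a call in 21 and gained one in 10. The planned mean of probe sets per gene, 1 probe set per gene and gene list tests were not run, since the files do not pair probe sets with genes. Signals near background limit what can be seen: 17 of the 673, 324 of the 8545 and 237 of the 5829 changed probe sets were among the dimmest 40%.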

Other observations

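A few control probe sets name mouse genes, and these were fitted apart from the comparisons, a test chosen after seeing the data. Transferrin receptor, which carries iron-loaded transferrin into cells, was dim. Its 3′ probe set stood at 22.6 ± 3.2 in untreated cells, 11.3 ± 1.8 with E. cuniculi and 21.5 ± 5.8 with C. parvum (SD, n = 3), where array medians were 10.9 to 16.1. The E. cuniculi value passed against untreated cells (log2 fold change -0.54, standard error 0.10, limma adjusted p = 0.00508, lower on 3 of 3 arrays). It missed the threshold with poly-A spike scaling together with the replicate block (-0.47, 0.0637) and in replicates 2 and 3 only (-0.54, 0.0535), with a fold change about as large, and the adjusted p ranged from 0.00251 to 0.0637 in 17 alternatives. The 5′ probe set stood at 9.7 ± 2.5 in untreated cells and 2.7 ± 2.3 with E. cuniculi, near the signals of up to 8.2 of the TrpnX probe sets, negative controls of the array. The middle probe set, at 4.9 ± 5.0 and 2.4 ± 2.2, did not pass (log2 fold change -0.18, limma adjusted p = 0.63).

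The 5′ control probe set of 18S ribosomal RNA, which has no poly-A tail, varied widely among untreated arrays, at 216.9, 4741.6 and 2476.4 on replicates 1, 2 and 3. It stood at 157.1, 355.3 and 313.2 with E. cuniculi and at 157.0, 950.4 and 753.1 with C. parvum. Its log2 fold change with E. cuniculi was -2.37 with a standard error of 1.08 and did not pass (adjusted p = 0.182). It passed with the replicate block (-2.37, adjusted p = 0.0219), with replicate 1 as a covariate (0.0161), with poly-A spike scaling added to that block (-2.31, 0.022), in replicates 2 and 3 only (-3.39, 0.00282) and without untreated replicate 1 (-3.75, 0.00914), over a range of 0.00282 to 0.478 in 17 alternatives. Beta-actin and Gapdh did not pass in any comparison. Their 3′ log2 fold changes with E. cuniculi were -0.01 and 0.00 after quantile normalization and 0.38 and 0.26 as deposited, which did not pass either (adjusted p = 0.138 and 0.135), with ranges of 0.0984 to 0.985 and 0.135 to 1.0 over the alternatives.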
